A study of Mycolicibacterium smegmatis with 6 samples.

How the data were processed

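Total RNA of Mycobacterium smegmatis MC2 155 wild type and crp2 mutant was sequenced in 6 libraries, 3 per strain. Per the labels' protocols the strains were shaken at 200 rpm and 37 °C to an optical density of 2.0 to 2.1, RNA was extracted with TRIzol, and libraries were made with the Illumina TruSeq RNA v2 kit and sequenced on an Illumina HiSeq instrument. That kit does not mark the strand, so reads of a gene and of an antisense or overlapping transcript cannot be told apart. Samples were assigned to strains from their titles.

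Per the file headers, the authors deposited one table per library with the read count of each gene, its start and end on the MC2 155 chromosome, and an RPKM value. The counts are whole numbers with no normalization. The deposited RPKM values are reads per kilobase of gene scaled by the total of the library, and from the values the total behind them is close to the sum of the counts. FastQC 0.11.5, Trimmomatic 0.32 and Bowtie 1.1.2 are named in the submitters' processing notes without role or order. The counting tool, its strand setting and its treatment of reads that map to several genes are not given in the sources used here, so values of genes with near-identical copies are uncertain.

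Each table listed the same 6507 genes and the lowest count of any gene in any library was 1. A gene with no reads in one strain would not be found in such a table. The wild-type tables each held 215 blank lines, which carry no counts and were dropped. Totals ranged from 2250256 to 16945048 counts. Between 7.65% and 11.6% of counts came from the transfer-messenger RNA, and the deposited tables held at most 0.198% ribosomal RNA and 0.0845% transfer RNA per library. Genes with at least 10 counts numbered 5625 in the shallowest library and 6442 in the deepest.

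Locus tags were matched to the RefSeq gene table of assembly ASM1500v1, which gave an entry for 6264 genes and a symbol for 976. Only those symbols are used as gene names, except that crp2 is named as in the labels and its paralog MSMEG_6189, which has the same symbol crp in the table, is called crp1. A symbol shared by several genes is replaced by the locus tag. The table holds no product names and no genome was used.

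Expression was compared with edgeR 4.0.16 in R 4.3.3 on the counts: TMM factors, genes kept by filterByExpr (6324), a robust quasi-likelihood fit on strain alone, and Benjamini-Hochberg adjustment at 0.05. The SE is the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled totals. The common dispersion corresponds to a biological variation of 16.1% between libraries, which with 3 per strain limits what small changes can be called.

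The design, the tests, the alternatives, the rule for named genes and 39 gene lists were fixed before the data were examined. Of these lists, 26 were given by locus number from prior knowledge and 13 by product words. With no products to match, 5 of the 13 were filled from gene symbols after the tables had been seen and 8 were not analysed here, so that 31 lists were tested. Members given by locus number could be checked by symbol only, and 1 was dropped from the hydrogenases because its symbol names another protein. Sets were tested with camera in limma 3.58.1 at a preset correlation of 0.01 for lists with at least 3 tested genes, with adjustment over lists.

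Named genes were crp2 and crp1, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between strains. They also included up to 4 called genes with the largest change per list, the most abundant member of a list with no call, and called genes within 6 locus numbers of crp2. From these 88 and crp2 the text gives those that a list or comparison needs.

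Alternatives were the DESeq2 1.42.0 Wald test, limma voom, other scalings (DESeq2 size factors, total counts, upper quartile), no filter, a mean of at least 10 CPM, removal of ribosomal and transfer RNA genes, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Removal of all RNA genes, thinning to the smallest library and the use of locus-number lists alone were added after the data had been seen. Pairs of libraries of one strain differed by more than sampling noise (chi-square per degree of freedom of 13.9 to 57.8), so all were kept as separate replicates.

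The procedure was tested on simulated counts for the crp2 mutant against wild type comparison, with 6324 genes. Of these 200 were changed singly, and 50 more were moved together in 5 sets of 10. It recovered 22.4% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Of its 171 calls in all, 11.7% fell on unchanged genes, and it called 5 of 5 moved sets and 0 of 5 unmoved sets. The simulated genes were drawn independently of each other. In the real lists the estimated correlation between genes ran from 0.00891 (glycolysis and gluconeogenesis) to 0.964 (propane monooxygenase). The set counts of the simulation therefore do not measure how often a real list is called falsely.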

Results

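The transcriptomes of 2 strains of Mycobacterium smegmatis MC2 155, a fast-growing soil mycobacterium used as a laboratory model, were measured by RNA sequencing. One strain was the wild type and the other carried a mutation in crp2 (MSMEG_0539), which encodes a cAMP receptor protein, a transcription factor that binds cyclic AMP. Each strain was represented by 3 libraries. Both were cultured with air at 37 °C in 7H9 broth with glucose (0.2%) and a detergent, Tween 80 (0.02%), and were harvested at an optical density of 2.0 to 2.1. The wild-type libraries held 10192296, 16945048 and 5280644 counted reads over 6507 genes, and the mutant libraries 8456739, 2250256 and 6567467. Levels are given as normalised read counts (CPM, scaled to a common library total) as mean ± SD with n = 3 libraries per strain, and positions are those of the deposited gene tables on the MC2 155 chromosome.

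The question posed by the series was how gene expression differs between the strains under aerobic growth. The mutated gene was examined first. crp2 (618144 to 618818) fell from 124 ± 13.7 CPM in the wild type to 49.2 ± 1.24 CPM in the mutant, 2.51-fold lower (log2 -1.33, SE 0.12, n = 3 each, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.39e-04). Every mutant library lay below every wild-type library, with 433, 104 and 327 crp2 counts in the 3 mutant libraries. How the mutation was made is not given in the sources used here, so the remaining reads cannot be assigned to a part of the gene. The second cAMP receptor protein gene, crp1 (MSMEG_6189, 6256824 to 6257498), was at 503 ± 10.9 CPM in the wild type and 603 ± 42.6 CPM in the mutant, a difference that did not pass the test (log2 0.26, SE 0.11, edgeR adjusted p = 0.124). Of 12 genes on either side of crp2, MSMEG_0542 was the only one past the threshold, by all genes tested and adjusted over the list alone. It rose 1.75-fold, from 102 ± 5.41 to 178 ± 16.8 CPM. By camera the neighbours had adjusted p = 0.719, and a second neighbour also passed when wild type replicate 2 was left out.

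**Figure D1:**
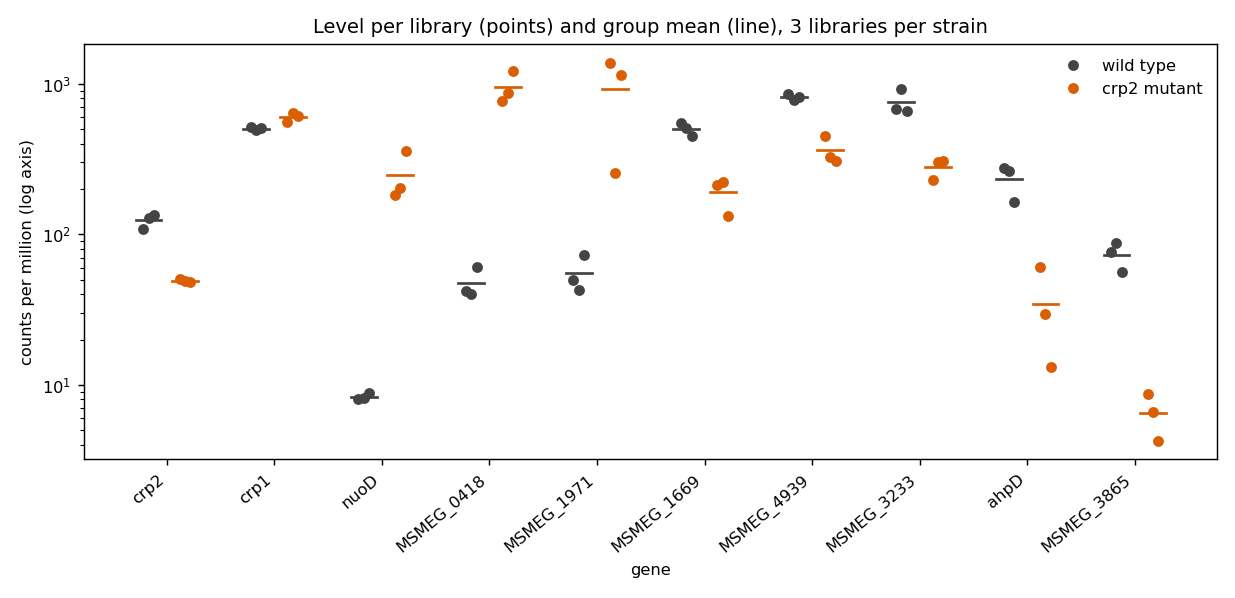
Levels of 10 genes in each library, in CPM on a log axis, with the 3 wild-type libraries in grey and the 3 mutant libraries in orange and a line at each group mean. crp2 and MSMEG_3865 lie lower in all 3 mutant libraries, nuoD lies 29.7-fold higher on fitted values, and MSMEG_1971 is higher in all mutant libraries but least so in replicate 2.

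The 2 strains differed widely. Genes of NADH dehydrogenase I, one succinate dehydrogenase locus, an alkane oxidation region and carbon monoxide dehydrogenase were among those that rose. All 8 ATP synthase genes, 2 of 4 cytochrome bd genes and 3 of 4 genes of the second succinate dehydrogenase locus were among those that fell. Of 6324 genes tested, 761 were higher and 560 lower in the mutant, together 1321 or 20.9% (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Large changes were mostly rises: 352 genes changed at least 2-fold, 303 of them higher and 49 lower. In 1309 of the 1321 genes the 3 mutant values did not overlap the 3 wild-type values. Being called favours this, so that count adds no support. Such separation held for 2472 of all 6324 tested genes, against the 10% that chance gives for 3 against 3. Genes can vary together between libraries, so the 2 shares are set side by side without a test. With upper-quartile scaling the calls split 854 higher and 395 lower, 68.4% higher against 57.6%. The counts also moved with 1 library left out, where fewer libraries were fitted. They rose to 912 higher and 785 lower genes without mutant replicate 1, and both fell without any other library. Every call shared with the fit of all libraries kept its direction. Higher genes numbered 502 without wild type replicate 1 and 485 without wild type replicate 2. Lower genes numbered 239 without wild type replicate 1, 239 without wild type replicate 2, 304 without wild type replicate 3, 369 without mutant replicate 2 and 232 without mutant replicate 3.

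Genes for the proton-pumping NADH dehydrogenase I, complex I of the respiratory chain, were higher. All 14 tested genes of the nuo locus (MSMEG_2050 to MSMEG_2063, 2127764 to 2143182) were higher in the mutant, by 10.2-fold to 29.7-fold, and all 14 also passed adjusted over the list alone. nuoD rose from 8.36 ± 0.428 to 246 ± 96.0 CPM, 29.7-fold (log2 4.89, SE 0.30, edgeR adjusted p = 1.34e-04). nuoE rose 27.9-fold (SE 0.51 on the log2 scale) and nuoF 24.0-fold, from 41.2 ± 6.13 to 989 ± 222 CPM. Wild-type levels of the smaller subunit genes were low, with nuoK at 1.17 ± 0.292 CPM. As a set the locus was called by camera with a preset correlation (adjusted p = 7.17e-51), with adjusted p = 0.158 with an estimated correlation.

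The 9 genes listed as succinate dehydrogenases, enzymes that feed electrons from succinate to menaquinone, went in opposite directions by locus. All 5 genes of MSMEG_0416 to MSMEG_0420 (492595 to 496745) rose, with a median of 20.1-fold. Within it MSMEG_0420 went from 11.3 ± 2.05 to 285 ± 59.7 CPM, 25.6-fold (log2 4.68, SE 0.21, edgeR adjusted p = 4.86e-06), and MSMEG_0418 from 47.6 ± 11.6 to 950 ± 229 CPM, 20.1-fold. In the locus MSMEG_1669 to MSMEG_1672 (1763124 to 1766560) 3 of 4 genes fell, and MSMEG_1669 went from 500 ± 49.2 to 190 ± 49.5 CPM, 2.64-fold lower (log2 -1.40, SE 0.19, edgeR adjusted p = 0.00115). In that second locus 2 genes passed without wild type replicate 1, 2 or 3 or mutant replicate 1 or 3, and 4 by DESeq2 and with total-count scaling. The list counts were 5 higher and 3 lower over all genes tested, and 5 higher and 4 lower adjusted over the list alone. camera called the list higher (adjusted p = 1.12e-08), with adjusted p = 0.158 with an estimated correlation.

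**Figure D2:**
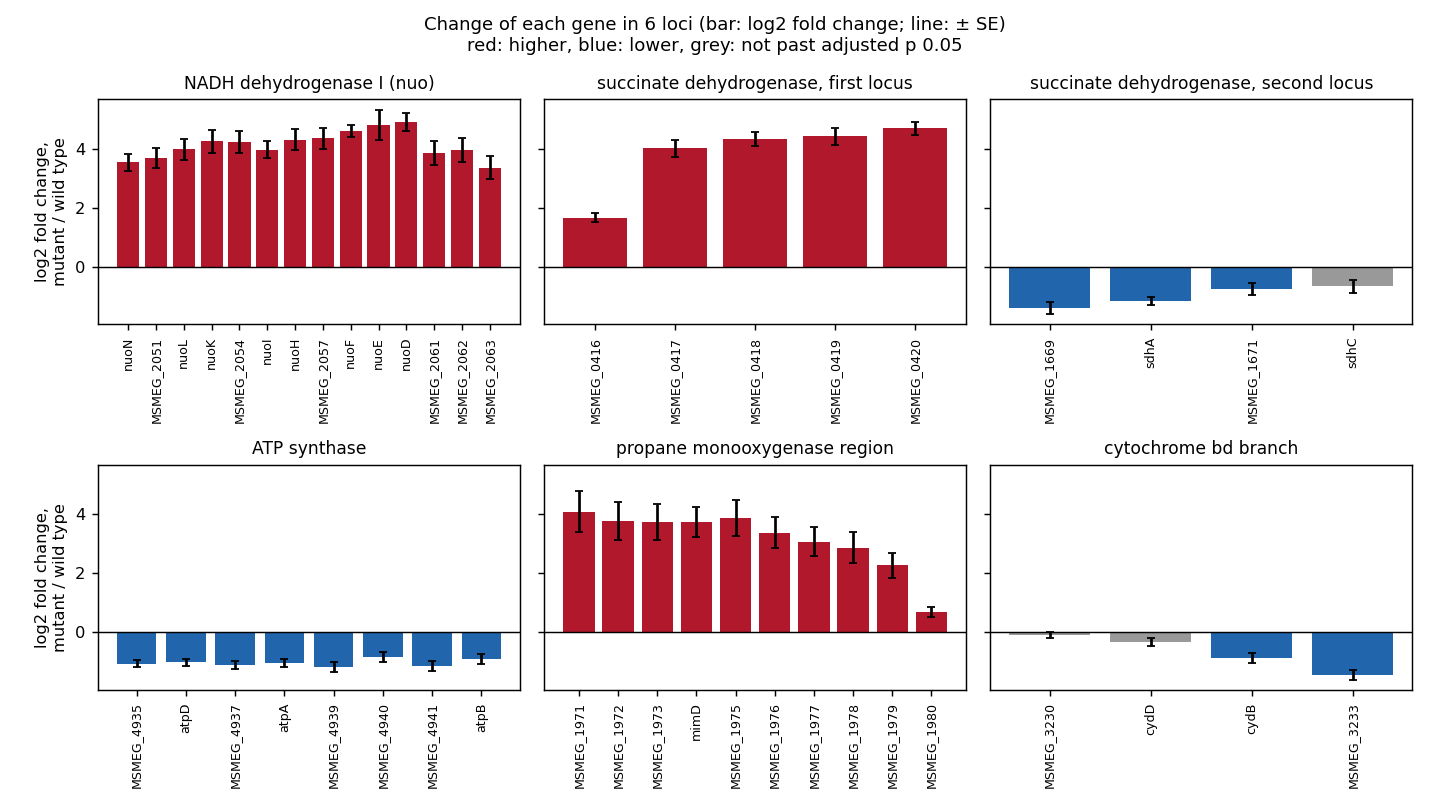
Log2 fold change (mutant over wild type) of each gene in 6 loci, as bars with lines of ± SE, in red where higher, blue where lower and grey where the adjusted p was not under 0.05. All 14 nuo genes and the 5 genes of the first succinate dehydrogenase locus are higher, the 8 ATP synthase genes are lower, and the 10 genes of the propane monooxygenase region are higher.

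ATP synthase genes, which encode the enzyme that makes ATP from the proton gradient, fell together. All 8 tested genes (MSMEG_4935 to MSMEG_4942, 5032225 to 5039696) were lower, by 1.78-fold to 2.25-fold, and all 8 were lower adjusted over the list alone. MSMEG_4939 fell from 815 ± 37.6 to 361 ± 78.3 CPM (2.25-fold, log2 -1.17, SE 0.16, edgeR adjusted p = 9.29e-04) and MSMEG_4935 from 308 ± 1.01 to 148 ± 16.9 CPM (2.08-fold). camera called the list lower with adjusted p = 3.56e-09, against adjusted p = 0.400 with an estimated correlation. In the cytochrome bd branch, an alternative terminal oxidase with its assembly transporter, 2 of 4 genes fell, the same number as adjusted over the list alone. MSMEG_3233 dropped 2.69-fold, from 752 ± 143 to 279 ± 42.1 CPM (log2 -1.43, SE 0.17, edgeR adjusted p = 4.94e-04), and cydB 1.83-fold. That list was called lower by camera (adjusted p = 0.0130), with adjusted p = 0.673 with an estimated correlation. In the cytochrome bcc-aa3 branch, the main route to oxygen, 1 of 7 genes, ctaE, passed over all genes tested and 3 did adjusted over the list alone (camera adjusted p = 0.102). ctaE was 1.56-fold lower, and its call was lost without wild type replicate 2 (adjusted p = 0.0657) and without mutant replicate 3 (adjusted p = 0.0654). The branch had 3 lower genes by DESeq2 and with total-count scaling and 2 by limma voom. Without wild type replicate 1 and without mutant replicate 2, 2 genes of that branch passed and camera called it lower, with adjusted p = 0.0257 and 0.0478.

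Genes listed for carbon monoxide dehydrogenase, which lets mycobacteria oxidise carbon monoxide, were all higher. The 6 tested genes (MSMEG_0744 to MSMEG_0749, 830754 to 836869) rose by 1.93-fold to 3.93-fold, and all 6 passed adjusted over the list alone. MSMEG_0746 rose from 19.4 ± 2.90 to 73.9 ± 22.5 CPM (3.88-fold, log2 1.96, SE 0.22, edgeR adjusted p = 4.22e-04), and MSMEG_0745 3.93-fold from a wild-type level of 2.40 ± 0.649 CPM. camera called the list higher (adjusted p = 5.16e-09), with adjusted p = 0.358 with an estimated correlation. No gene of this list has a symbol in the reference table, so its membership rests on recalled locus numbers. The same holds for part of other lists. Symbols were present for 8 of 14 nuo, 3 of 8 ATP synthase, 2 of 9 succinate dehydrogenase and 1 of 4 propane monooxygenase genes. With a mean of at least 10 CPM 2 of the carbon monoxide dehydrogenase genes were tested, both higher.

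The propane monooxygenase genes, for an enzyme that oxidises short alkanes, also rose. All 4 listed genes, MSMEG_1971 to MSMEG_1974, were higher by 13.4-fold to 16.9-fold over all genes and adjusted over the list alone. MSMEG_1971 rose from 55.0 ± 15.7 to 925 ± 592 CPM (16.9-fold, log2 4.08, SE 0.69, edgeR adjusted p = 0.0122) and mimD 13.4-fold (log2 3.74, SE 0.51, edgeR adjusted p = 0.00459). The spread among mutant libraries was wide because replicate 2 lay lower, with MSMEG_1971 at 4.62 times the wild-type mean there. Without wild type replicate 2 or without mutant replicate 1 the call held for 1 of the 4 genes, with MSMEG_1971 at adjusted p = 0.0621 and 0.0549, and without wild type replicate 3 for 3. Of the 10 genes of the region, MSMEG_1971 to MSMEG_1980, all were higher with all libraries. Of these, 4 were without wild type replicate 2 or mutant replicate 1, 7 without wild type replicate 1 or 3, and 9 without mutant replicate 3. camera called the list higher (adjusted p = 1.59e-04), with adjusted p = 0.596 with an estimated correlation and fry adjusted p = 0.0606.

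The largest falls outside these groups included MSMEG_3865, a small gene of 3938659 to 3938871 that the reference table did not match. It fell 11.1-fold, from 73.1 ± 15.9 to 6.54 ± 2.24 CPM (log2 -3.47, SE 0.28, edgeR adjusted p = 1.39e-04). Its neighbour cobN, whose product makes cobalamin by inserting cobalt, fell 3.11-fold, from 405 ± 57.5 to 131 ± 19.4 CPM. Falls of 2.65-fold to 3.17-fold were seen for MSMEG_3499, MSMEG_6540, MSMEG_3305 and MSMEG_1738, the last from 1161 ± 135 to 438 ± 136 CPM. In the list for oxidative stress defence, ahpD, an alkyl hydroperoxide reductase subunit, fell 6.67-fold from 234 ± 60.8 to 34.4 ± 24.0 CPM (log2 -2.74, SE 0.57, edgeR adjusted p = 0.0234), and the adjacent MSMEG_4891 fell 5.46-fold. The ahpD call was lost without wild type replicate 1 (adjusted p = 0.0607), wild type replicate 2 (0.0752) and mutant replicate 2 (0.0643), and its log2 change was -3.60 without mutant replicate 1. The MSMEG_4891 call was lost without any one library except mutant replicate 3, with adjusted p from 0.0535 (without mutant replicate 1) to 0.0844 (without wild type replicate 2). In the same list MSMEG_6384, a katG catalase-peroxidase gene, rose 1.68-fold from 632 ± 19.0 to 1059 ± 195 CPM. The 7 genes of the list counted 2 higher and 2 lower, and 4 higher and 2 lower adjusted over the list alone. Its median was log2 0.37, its mean -0.39 and the direction of camera up (adjusted p = 0.960). Its counts were 1 higher and 0 lower without wild type replicate 1, wild type replicate 2 or mutant replicate 2, 1 and 1 without wild type replicate 3, and 4 and 1 without mutant replicate 1.

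Lists for carbon metabolism were examined next. In the tricarboxylic acid cycle and glyoxylate shunt list, 1 of 12 genes rose and 1 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.960). The riser was MSMEG_3706 (symbol aceA, isocitrate lyase, 3770113 to 3772422), from 37.3 ± 6.44 to 168 ± 45.2 CPM (log2 2.18, SE 0.22, edgeR adjusted p = 3.99e-04). The gene that fell, MSMEG_5672 (log2 -0.47), kept its call only without mutant replicate 1 among the libraries left out, with adjusted p between 0.0539 (without wild type replicate 3) and 0.128 (without mutant replicate 3) in the rest, and lost it with upper-quartile scaling. DESeq2 and limma voom called 2 lower genes in that list. Without mutant replicate 1, 3 were lower, and without mutant replicate 3, 2 were higher. In the glycerol use list 2 of 5 genes rose, 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.60), and MSMEG_6761 rose 2.28-fold, from 2314 ± 527 to 5279 ± 1004 CPM. That count was 1 without wild type replicate 1, wild type replicate 3, mutant replicate 2 or mutant replicate 3, and 1 gene was lower without wild type replicate 1, mutant replicate 1 or mutant replicate 2, with total-count scaling and by DESeq2. The methylcitrate cycle list, for propionate use, had 0 of 4 genes past the edgeR threshold, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom.

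Glycolysis and gluconeogenesis counted 2 higher and 1 lower of 7 genes, 3 and 1 adjusted over the list alone, and the higher fbaA was at 76.9 ± 7.41 and 112 ± 10.4 CPM (1.46-fold). The fbaA call was lost without wild type replicate 2 (edgeR adjusted p = 0.0584), where no gene of the list passed. Without wild type replicate 1, wild type replicate 3 or mutant replicate 3 the list counted 1 higher and 0 lower, without mutant replicate 2 it counted 2 and 0, and after thinning 1 and 1. For trehalose metabolism and recycling the count was 3 higher of 9, also 3 adjusted over the list alone, all in the sugar importer locus MSMEG_5058 to MSMEG_5061 and led by MSMEG_5061 (1.35-fold). Those 3 calls were lost without wild type replicate 1, 2 or 3 and without mutant replicate 3, with MSMEG_5061 at adjusted p = 0.101, 0.0657, 0.0710 and 0.0743. The trehalose count was 2 without mutant replicate 2 and 4 without mutant replicate 1, and 1 with total-count scaling or after thinning. camera called neither list, with adjusted p = 0.960 for glycolysis and 0.651 for trehalose.

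Genes linked to cAMP counted 3 higher and 3 lower of 16, crp2 itself among the lower, and 3 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.220). MSMEG_3811, a universal stress protein known to bind cAMP, fell 2.34-fold from 400 ± 79.2 to 172 ± 16.5 CPM (log2 -1.22, SE 0.16, edgeR adjusted p = 7.18e-04), and MSMEG_4279 rose 1.59-fold. Without wild type replicate 1 or wild type replicate 2, 1 gene was higher. The glycopeptidolipid locus, which makes surface lipids, had 8 of 32 genes higher and 0 lower, with the same counts adjusted over the list alone. There mtf2 (443164 to 443967), a methyltransferase gene, rose 2.47-fold from 198 ± 19.8 to 488 ± 62.1 CPM (log2 1.30, SE 0.13, edgeR adjusted p = 2.82e-04) and MSMEG_0389 1.67-fold. By camera the glycopeptidolipid list had adjusted p = 0.103, and by fry, which asks whether its genes move one way, 0.0158. At an unadjusted p under 0.05, 2 of its genes were lower, and DESeq2 and limma voom called 0 lower.

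In the nitrogen assimilation list 1 of 23 genes rose and 4 fell, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.220). MSMEG_2188 was lower by 2.24-fold, from 405 ± 0.234 to 180 ± 36.0 CPM, and MSMEG_2426 higher by 1.64-fold. Without wild type replicate 1, 2 or 3 or mutant replicate 3 the list held 1 lower gene, and without wild type replicate 1 or mutant replicate 1 it held 2 higher genes. With upper-quartile scaling or a mean of at least 10 CPM the nitrogen counts were 2 higher and 2 lower. The phosphate transport list counted 2 higher and 4 lower of 9 both ways, with regX, a response regulator gene, 1.42-fold lower (156 ± 9.90 and 110 ± 2.31 CPM). Its median was log2 -0.05, its mean 0.06 and its camera direction down (adjusted p = 0.809), and the median was 0.00 with upper-quartile scaling and 0.03 without mutant replicate 3. For phosphate, 1 gene was lower without wild type replicate 1, 2 or 3 or mutant replicate 2, 2 were without mutant replicate 3, and 1 was higher without wild type replicate 1, wild type replicate 2 or mutant replicate 3. It had 1 higher and 1 lower after thinning, and 1 and 3 with a mean of at least 10 CPM. The iron acquisition list had 5 higher and 1 lower of 32 both ways (camera adjusted p = 0.809), among them MSMEG_0014 (1.92-fold higher, 12.7 ± 1.29 and 23.8 ± 3.14 CPM). The MSMEG_0014 call was lost after thinning (log2 0.52, adjusted p = 0.0726), where the list held 1 higher and 0 lower genes. Higher iron genes numbered 1 without wild type replicate 2 or mutant replicate 3, 3 without wild type replicate 3 and 2 without mutant replicate 2, and of these fits the 1 lower call held without mutant replicate 2 only. Lower iron genes numbered 0 by DESeq2, with upper-quartile scaling and with a mean of at least 10 CPM, and 2 by limma voom. In sulfur assimilation cysT was the 1 gene of 4 that passed (1.35-fold lower, with 2 lower adjusted over the list alone and camera adjusted p = 0.396). Its call was lost with upper-quartile scaling (adjusted p = 0.0663), with a mean of at least 10 CPM (0.0620), after thinning (0.112) and without wild type replicate 1, 2 or 3 or mutant replicate 1 or 3, with adjusted p from 0.0696 (without mutant replicate 1) to 0.181 (without mutant replicate 3), and 2 genes passed without mutant replicate 2, by DESeq2, by limma voom and with total-count scaling.

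Genes for translation were examined as 2 lists. Of 50 ribosomal protein genes, 0 passed by edgeR, 0 had an unadjusted p under 0.05, and 0 passed by DESeq2 or limma voom. Their median was log2 0.04 and their mean 0.04 while the camera direction was down (adjusted p = 0.960), and the median was -0.04 without wild type replicate 2. Aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, had 8 of 16 lower and 10 of 16 lower adjusted over the list alone. hisS fell from 375 ± 13.1 to 217 ± 13.9 CPM, 1.73-fold (log2 -0.79, SE 0.11, edgeR adjusted p = 9.83e-04). That count was 1 without wild type replicate 1, 2 without wild type replicate 2, mutant replicate 2 or mutant replicate 3, 5 without wild type replicate 3, and 5 with upper-quartile scaling. camera called the list lower (adjusted p = 0.00201), with adjusted p = 0.778 with an estimated correlation and fry adjusted p = 0.0583. The cobalamin and molybdopterin synthesis list, for enzyme cofactors, had 4 of 11 genes lower and 1 higher, with the same counts adjusted over the list alone. cobN, cobF (1.71-fold) and cobO (1.57-fold) fell, and mobA rose 1.76-fold from 25.8 ± 2.55 to 44.9 ± 6.18 CPM. Its camera call (lower, adjusted p = 0.0333) was lost with an estimated correlation (adjusted p = 0.673), with a mean of at least 10 CPM (0.0738), without mutant replicate 2 (0.0576) and without mutant replicate 3 (0.0913).

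In the DosR regulon core, genes induced by low oxygen, MSMEG_5246 was the 1 of 30 that passed (7097 ± 938 and 5038 ± 331 CPM, 1.41-fold lower), and adjusted over the list alone 0 passed by edgeR, with 3 at an unadjusted p under 0.05, 3 called by DESeq2 and 1 by limma voom over all genes. camera called the DosR list lower (adjusted p = 0.00941), a call lost without wild type replicate 2 (adjusted p = 0.0551), without mutant replicate 1 (0.205), by fry (0.369) and with an estimated correlation (0.937). The MSMEG_5246 call was lost without wild type replicate 1 (adjusted p = 0.0876), wild type replicate 2 (0.127), mutant replicate 2 (0.0695) and mutant replicate 3 (0.109), and 4 DosR genes were lower without mutant replicate 2 and 2 with total-count scaling. Of 46 tested genes tied to the general stress sigma factor SigF, 2 were higher and 1 was adjusted over the list alone, with MSMEG_1791 (symbol usfY) at 50.4 ± 6.38 and 100 ± 9.0 CPM (2.00-fold, edgeR adjusted p = 7.36e-04). Without mutant replicate 1, 23 SigF genes were higher and the list moved from camera adjusted p = 0.809 to 2.34e-05, and without any other single library except mutant replicate 2, and with total-count scaling, the count was 1. Heat shock and chaperone genes counted 2 higher of 9, groES (1.48-fold) and MSMEG_1583 (symbol groL, 1.57-fold), and 3 adjusted over the list alone (camera adjusted p = 0.503). Both chaperone calls were lost without wild type replicate 1, 2 or 3 and without mutant replicate 3. There groES had edgeR adjusted p = 0.135, 0.0590, 0.0813 and 0.107 and MSMEG_1583 0.113, 0.0689, 0.0636 and 0.0981. Without mutant replicate 2, 3 genes of the list passed. Another gene with the symbol groL, MSMEG_1978 of the propane monooxygenase region, is not in this list. With all libraries it was also called higher, and in mutant replicate 2 it was at 2.58 times the wild-type mean.

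Hydrogenase genes, for hydrogen oxidation, had 1 of 26 lower both ways (MSMEG_2266, 1.48-fold, camera adjusted p = 0.102 for the list). That call was lost without wild type replicate 2 (edgeR adjusted p = 0.0675), without mutant replicate 3 (0.0669) and after thinning (0.0734). The hydrogenase list was called lower by camera without wild type replicate 1, wild type replicate 3 or mutant replicate 2 (adjusted p = 0.0327, 0.0429 and 0.0329), and without mutant replicate 1 it also held 1 higher gene, as it did with upper-quartile scaling, with a mean of at least 10 CPM and after thinning. Among mycolic acid and fatty acid synthase genes, MSMEG_4757 was the 1 of 8 that fell, both ways, from 10928 ± 814 to 7487 ± 888 CPM (1.46-fold, camera adjusted p = 0.152 for the list). Its call was lost without wild type replicate 1 (adjusted p = 0.0839) and wild type replicate 2 (0.0789), and without mutant replicate 2 the list had 3 lower genes and a camera adjusted p of 0.0489. By edgeR, 0 of 7 SOS response genes, 0 of 5 sigma factor genes and 0 of 3 alanine and proline dehydrogenase genes passed, over all genes and adjusted over the list alone. At an unadjusted p under 0.05 these lists held 2, 1 and 1 genes, and DESeq2 and limma voom called 0 in each. recA, the DNA damage recombinase, was at 246 ± 11 and 251 ± 12.8 CPM. The SOS list held 1 lower gene without mutant replicate 1, and the alanine and proline list 1 higher gene without wild type replicate 3.

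**Figure D3:**
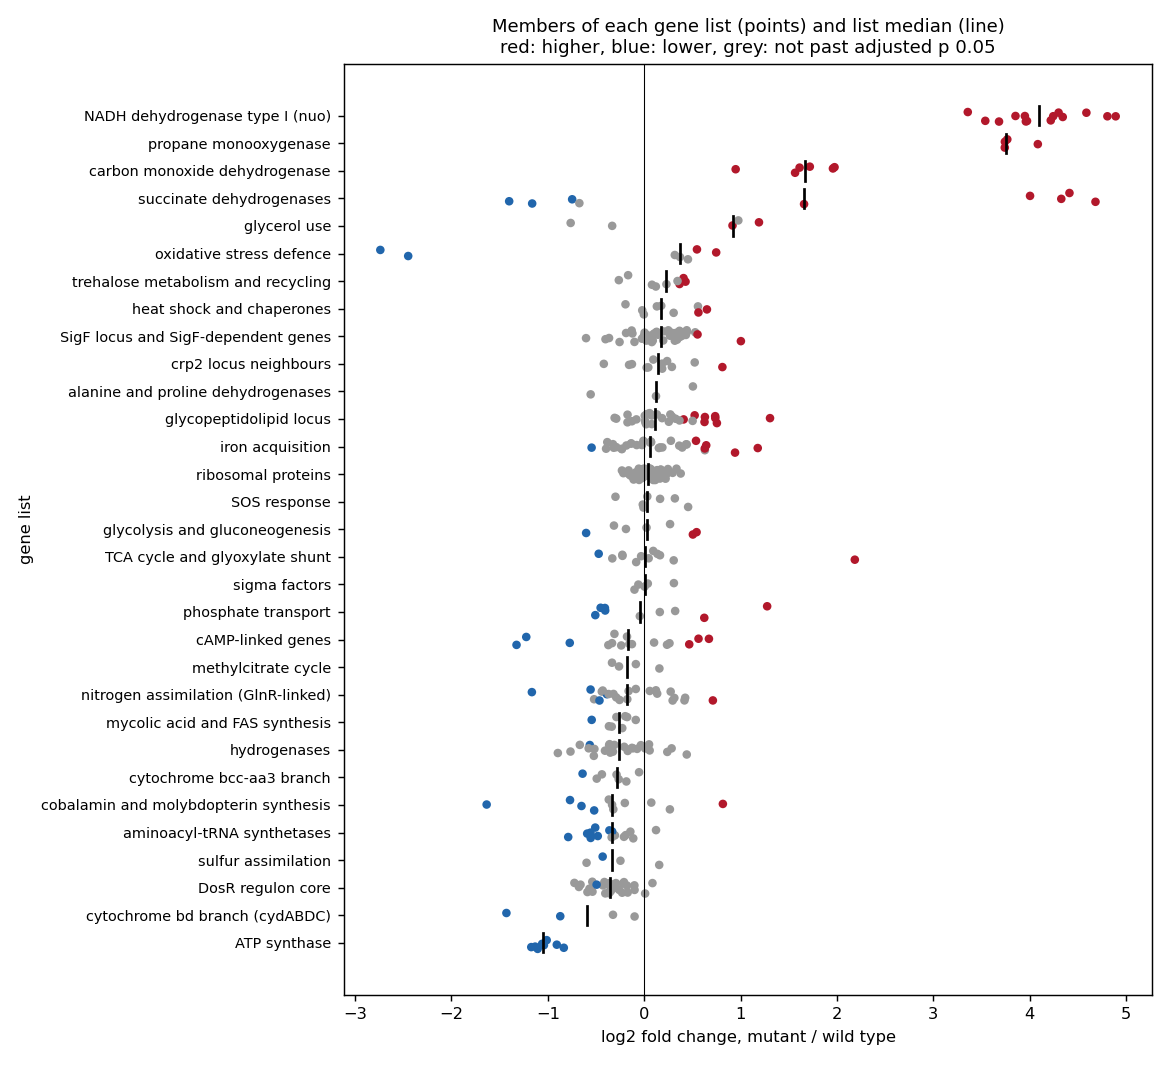
Log2 fold change (mutant over wild type) of every tested member of 31 gene lists, as points, with a line at each list median and colours as higher (red), lower (blue) or not past an adjusted p of 0.05 (grey). The nuo, propane monooxygenase and carbon monoxide dehydrogenase members all lie above 0, the ATP synthase members all lie below 0, and the succinate dehydrogenases fall on both sides.

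Over the 31 lists, camera with a preset correlation of 0.01 called 4 higher and 5 lower. With an estimated correlation 0 lists were called, 3 had an unadjusted p under 0.05, and fry called 7. The wording on each list above therefore rests on its count of single genes. The labels do not say that the 3 libraries of a strain came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.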

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

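The alternatives were fixed before the data were examined, except all RNA genes removed, thinning and locus-number lists alone, which were chosen after. Over 88 named genes besides crp2, 1337 of 1490 values kept direction and side of the threshold, 147 lost the call, mostly with a library left out, and 6 changed sign. Those 6 belong to genes that did not pass: rpsA (MSMEG_3833, log2 -0.02) was at 0.028 with upper-quartile factors, 0.018 with a mean of at least 10 CPM and from -0.054 to 0.067 with a library left out, above 0 without wild type replicate 3 or mutant replicate 3. pruA (MSMEG_5119, 0.12) ranged from -0.11 to 0.29 with a library left out, below 0 without wild type replicate 2 or mutant replicate 3, and the cause was not tested. With a library left out, higher genes ranged from 485 to 912, lower genes from 232 to 785, genes changed at least 2-fold from 291 to 421, crp2 from log2 -1.41 to -1.24 and lists from 8 to 11. Fewer libraries were fitted in these runs. The 912 higher and 785 lower genes were found without mutant replicate 1, and the cause of the rises was not tested. Every other setting stayed within 1.5 times the main counts, except that the number of lists called was 0 with an estimated correlation, where a list is charged for how its own genes vary together. DESeq2 called 756 higher and 541 lower genes and limma voom 768 and 576, and thinning to the smallest library, which tested 5714 genes, left 580 and 384.

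The values did not show that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at -0.01, -0.03 and 0.20 over genes, and of the 3 numbers only replicate 3 correlated best with its own. With 3 numbers such a check cannot exclude pairing. With the number as a block, 724 genes were higher, 540 lower and 340 changed at least 2-fold, crp2 was at log2 -1.32 and 9 lists were called. With that block 4 named genes lost their edgeR call. They were cysT (adjusted p = 0.0524), MSMEG_2187 (0.0518) and MSMEG_2425 (0.0644) of the nitrogen list, and MSMEG_5059 of the trehalose list (0.0620). The block with a GC correction was not run because no genome was used, and pseudocounts do not apply to counts.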

Other observations

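Gene groups outside the fixed lists also moved side by side. These runs of neighbouring genes, and all tests below except those of other splits of the libraries, were chosen after the values had been seen. The runs rest on the fit with all libraries and were not followed with a library left out. One stretch of 13 genes ran from MSMEG_1704 to MSMEG_1716 (1797877 to 1812956), with the sugar-use genes chvE, araA and araB. It also holds genes with the symbols mmsA and mmsB, whose products the reference table does not name. Every gene of the stretch was called higher, by 1.62-fold to 5.19-fold with a median of 3.09-fold. A stretch of 5 genes with xylA, xylose isomerase (MSMEG_6018 to MSMEG_6022), was higher by a median of 3.19-fold. The ehuA to ehuD genes, named for an ectoine importer, lay in a run of 5 higher genes with a median of 1.65-fold. Long runs without a symbol were MSMEG_1138 to MSMEG_1151 (14 genes, median 2.43-fold) and MSMEG_4162 to MSMEG_4174 (13 genes, 2.71-fold). A run of 10 genes with fadD5, MSMEG_0130 to MSMEG_0139, had a median rise of 2.06-fold.

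Other runs were lower. Their calls are less sure, since lower genes ranged from 232 to 785 with a library left out. The 5 genes egtA to egtE, for ergothioneine synthesis (6311487 to 6316813), were lower by 1.35-fold to 1.5-fold. mutA, scpA and meaB, for methylmalonyl-CoA metabolism, lay in a run of 4 lower genes with a median of 1.84-fold. The tryptophan synthesis genes trpC, trpB and trpA ran with lgt (median 1.53-fold), and murC, murG and ftsW, for cell wall synthesis and division, lay in a run of 4 (1.46-fold). The ATP synthase run extended to 12 genes, MSMEG_4932 to MSMEG_4943, and included murA. In all, 58 runs of at least 4 called genes of one direction were found, 41 higher and 17 lower, with 332 genes. Random placement of the same calls gave a median of 1 run and at most 10 (permutation p = 1.00e-04, the smallest that 10000 permutations can give), so calls scattered singly along the chromosome are argued against. That placement treats neighbouring genes as independent, so it does not bear on any single run or on the cause of the runs.

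The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 761 higher genes, 560 lower and 352 changed at least 2-fold, and for each it was the 1 split of 10 with a count as large. The highest other split gave 0 by edgeR, with 58 to 399 genes at an unadjusted p under 0.05 in the 9 other splits, at most 8 called by DESeq2 and 0 by limma voom. Each other split mixes the strains in both groups, so the strain difference widens the spread within them. Their low gene counts are therefore no measure of false calls. For lists called by camera, 5 of the 10 splits gave as many as the real 9, and the highest other gave 12.

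The first pattern weighed is that crp2 reads remain in the mutant at a ratio of 0.399. If wild-type cells in the mutant cultures supplied them, no gene should fall below that ratio, and 2 called genes had an upper 95% bound below it, MSMEG_3865 (0.0903, upper bound 0.140) and ahpD (upper bound 0.398). After adjustment over all 6324 genes tested no gene passed a test of lying below the crp2 ratio (smallest adjusted p = 0.216), so a single low gene does not decide. Reads shared with the paralog crp1 would make crp2 a fixed share of crp1, and the share was 9.08%, 7.64% and 7.87% in the mutant libraries (chi-square p = 0.104), against 21.1% to 26.7% in the wild type. Any pair of steady genes gives such a share, so neither explanation can be told apart from a transcript of part of the gene, which stays open and untested.

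The second pattern is that called genes below the median level of 38.7 CPM were mostly higher (389 of 501, 77.6%). Background reads in the mutant libraries are argued against, since 92.0% of the 389 rose by more than 2.71 RPKM, the highest 5th percentile in a mutant library. Lower depth is too, since 82.3% of the called genes in that group were higher after thinning, and so is the scaling, with at least 78.8% under the other scalings. Why these called genes were mostly higher stays open and was not tested further. Called genes above that level were more often lower (448 of 820), but this depended on the scaling: 54.0% were lower with DESeq2 size factors, 56.0% with total counts, and 43.3% (317 of 732) with upper-quartile factors, which shift all genes towards higher. After thinning 334 of 681 were lower, 49.0%, with a 95% interval of 45.2% to 52.9%, so lower depth is not settled and no direction is claimed for these genes.

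The third pattern is that the 10 genes MSMEG_1971 to MSMEG_1980 rose less in mutant replicate 2, at 0.194 to 0.641 of the mean of the other mutant libraries. Counting error at that depth is argued against, since for 10 of 10 genes the upper 95% counting bound lay below 1. The other 294 genes called higher at least 2-fold had a median ratio of 0.964, so most of them did not share the drop. They were called with replicate 2 included, which favours genes that stayed high there. A difference of the whole library is therefore not settled by them. A difference between cultures could account for the smaller rise of the 10 genes and was not tested, since the labels give no culture for a library.

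The first principal component held 60.9% of the variance and separated the strains, and the next, with 15.6%, set mutant replicate 1 (-20.1) apart from mutant replicate 2 (19.0). Of the genes tied to SigF, 23 were called higher without mutant replicate 1, against 2 with all libraries.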
